A study of Mus musculus with 10 samples.

How the data were processed

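RNA was measured in 10 libraries of sorted mouse blood neutrophils, 2 in each of 5 groups. Per the labels' protocols, total RNA was extracted with a column kit, cDNA was made with the SMART-Seq v4 Ultra Low Input kit and fragment libraries with an Ion Xpress Plus kit. The authors deposited RPKM values, reads scaled to the length of the gene model and to the total of the library, with a column for each library. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the treatment of reads with several matches are not given in the sources used here, so values of close paralogs such as the hemoglobin, Ms4a6 and Stfa genes are uncertain. Strand use in counting is not given either. Gene identifiers of 54079 of the 54146 genes (99.9%) were found in a GENCODE annotation of the same build, and 97.7% of those had the same start and end.

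Depth was recovered from the values. In each library the RPKM of a gene is a whole number of reads times a step set by its length and the library total. With a tolerance of 0.02 reads, 84.7% of values above 0 came out whole, and 89.7% of those of at most 20 reads. The totals lay between 13765576 and 15514537 reads, a ratio of 1.13, and 1 read in a gene of 1 kb was worth 0.0726 RPKM at the lowest total. The main results use the RPKM values as deposited. The test had been planned for counts, with limma for a normalized unit, and the unit was RPKM, so the count tests planned as alternatives were not run.

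Genes with at least 1 RPKM in at least 2 libraries were tested, which left 8039. The values were transformed as log2(RPKM + 1), so fold changes understate the change of low genes. One limma model with trend and robust settings held the 5 group means, sharing 1 estimate of the spread, with 5 residual degrees of freedom. Contrasts were the mean of the 3 OS5K groups against OSPa and against sham, OSPa against sham, each OS5K line against OSPa, and an F test among the OS5K lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors given as SD are between libraries, and SE is that of the limma contrast. For list scores and their differences, SE comes from the pooled spread of the score within groups, without limma. In differences between scores the erythroid score leaves out Hba-a2.

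Before the data were examined, 35 gene lists were fixed, covering neutrophil functions, signalling responses and markers of other blood and tissue cells. Of these, 29 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Calls by fry are those of its test for a shift of a list in a common direction. The rule for named genes was also fixed then: per main comparison, up to 10 called genes of largest rise and of largest fall among those whose libraries do not overlap and whose mean is at least 5 RPKM, leaving out predicted genes. Where none passed, the 5 of smallest p in that direction were given as values. For single lines the first 3 were named, for the test among lines the 5 of smallest p, for each list up to 4 members of smallest p, and 7 neutrophil genes in every comparison. Some genes that this rule names are not reported here, though they stay in the counts and lists. Called genes outside this rule and the abundant monocyte genes were chosen after their values were seen, as was the test of the hemoglobin share.

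Alternatives were a replicate block, quantile normalization, median centring, limma without trend, no filter, a filter at 5 RPKM, pseudocounts of 0.1 and 5, fits with only the groups compared, a 2-fold minimum, each OS5K line left out of the mean, and each library left out in turn. Added after the data were seen were limma-voom on the recovered reads (where 6 tested genes without a known length counted as 0), RPKM rescaled to reads outside the 4 adult hemoglobin genes, Hba-a1 and Hba-a2 added together, and a crossed pairing.

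The scripts were tested on simulated counts with 200 changed genes per run and 10 runs per comparison. For OS5K against OSPa, 66.8% of 2-fold and 93.0% of 4-fold changes were recovered, and 5.03% of calls were unchanged genes. For OSPa against sham the shares were 49.5%, 85.2% and 6.32%, for OS5K against sham 66.7%, 93.2% and 5.03%. The type I interferon list, shifted 1.5-fold, was called in 10 of 10 runs by each of the 3 list tests. In the data its members had an estimated correlation of 0.53, so these runs do not give the power of the list tests there. Simulated genes were independent, so neither the preset correlation nor the shares of calls were tested under the correlation of real genes. For OS5K against OSPa or sham, all OS5K libraries got the same change, with no spread between lines. The shares of unchanged genes among the calls therefore do not cover that spread. The median SE for OS5K against OSPa was 0.125 in the simulation and 0.135 in the data, so the recovered shares may be too high. Tools were R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.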

Results

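Neutrophils were sorted as CD11b+ Ly-6G+ cells from the blood of BALB/c nu/nu mice, a strain without a functional thymus that accepts human tumour cells. Blood was taken 14 days after vehicle or human kidney cancer cells had been placed in the kidney. OS-RC-2 is a human clear cell renal cell carcinoma line. The labels name the injected lines as OSPa and as OS5K #1, OS5K #2 and OS5K #3, and the series speaks of OS-RC-2 and lines derived from it. OSPa was read here as the parental line and the 3 OS5K lines as its derivatives. Each of the 5 groups, vehicle (sham) included, had 2 libraries, which makes 10 libraries of polyadenylated RNA amplified with SMART-Seq v4. The table gave RPKM for 54146 genes, of which 23227 were above 0 in any library. Read totals recovered from the RPKM steps lay between 13765576 and 15514537 reads per library. Replicates of a group differed by more than the counting noise of reads, the only noise this measure covers. The median chi-square per gene lay between 2.24 and 3.39 and the mean, raised by a minority of genes, between 18.3 and 48.8. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

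The libraries were rich in neutrophil transcripts in every group. The mean RPKM in sham libraries was 38441 ± 599 (SD, n = 2) for S100a9 and 20959 ± 1648 for S100a8, whose proteins form calprotectin, the major cytosolic protein of neutrophils. Cxcr2, the receptor for neutrophil-attracting chemokines, stood at 765 ± 1.83 in sham, 855 ± 12.5 in OSPa and 760 ± 37.2 in the 6 OS5K libraries. None of these genes was called in any comparison of groups, nor were Ly6g and Itgam, which encode the proteins used for the sort, Mmp9, a secreted gelatinase, or Il1b, the cytokine interleukin-1 beta (limma, 7 genes). Their log2 fold changes for OS5K over OSPa ran from -0.30 for Mmp9 to 0.14 for Itgam.

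The series compares neutrophils of mice bearing OS-RC-2 and its derivatives, so the first comparison set the mean of the 3 OS5K groups against OSPa. Some genes of red blood cells and of monocytes were called higher in the OS5K libraries, and no gene was called lower. As lists, neither the red cell nor the monocyte markers were called with an estimated correlation (adjusted p = 0.25 for both). Fech, the last enzyme of heme synthesis, rose from 38.4 ± 8.57 RPKM in OSPa (SD, n = 2) to 111 ± 43.7 in OS5K (SD, n = 6), a log2 fold change of 1.45 (SE 0.21, limma adjusted p = 0.030). Ms4a4a, a membrane protein of macrophages, rose from 0.383 ± 0.430 to 10.2 ± 5.54 RPKM, a log2 fold change of 2.91 (SE 0.31, adjusted p = 0.0077). In mm10, the Fech gene (ENSMUSG00000024588) spans chromosome 18 from 64456550 to 64489066 and Ms4a4a (ENSMUSG00000101389) chromosome 19 from 11375523 to 11392790. The values are given per gene and not per transcript. In reads, Ms4a4a had 8 and 1 in the OSPa libraries and between 65 and 227 in the OS5K libraries. The test called 28 of 8039 genes, all of them higher in OS5K, and 24 of the 28 by at least 2-fold. At an unadjusted p under 0.05 there were 634 genes, 480 higher and 154 lower, where 402 would be expected by chance.

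All 28 genes also had a lower mean in OSPa than in sham. They were chosen for low values in the same OSPa libraries, and none of them was called for OSPa against sham. Fech stood at 74.5 ± 5.10 RPKM in sham (SD, n = 2), and at 154, 95.3 and 82.6 in the means of OS5K #1, #2 and #3. The calls rested on both OSPa libraries. Without OSPa replicate 1 none of the 28 was called and 1 other gene was, and without OSPa replicate 2 the count was 5, of which 2 were among the 28. It was 60 without OS5K #1 replicate 2, 15 without OS5K #2 replicate 1 and 15 without its replicate 2, and 7 without either replicate of OS5K #3. With no filter on low values, 15 genes were called, 4 higher and 11 lower, and with OS5K #1 left out of the OS5K mean 13 were. The error covers libraries within a line, not the spread between lines, and 1 parental line stands against 3 derivatives. At an unadjusted p under 0.05 (limma F test), 21 of the 28 and 535 of all 8039 genes differed among the OS5K lines, none after adjustment over all genes. This test shares its error estimate with the one that chose the 28, which favours genes of small error. The 21 therefore do not show that the lines differ.

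**Figure D1:**
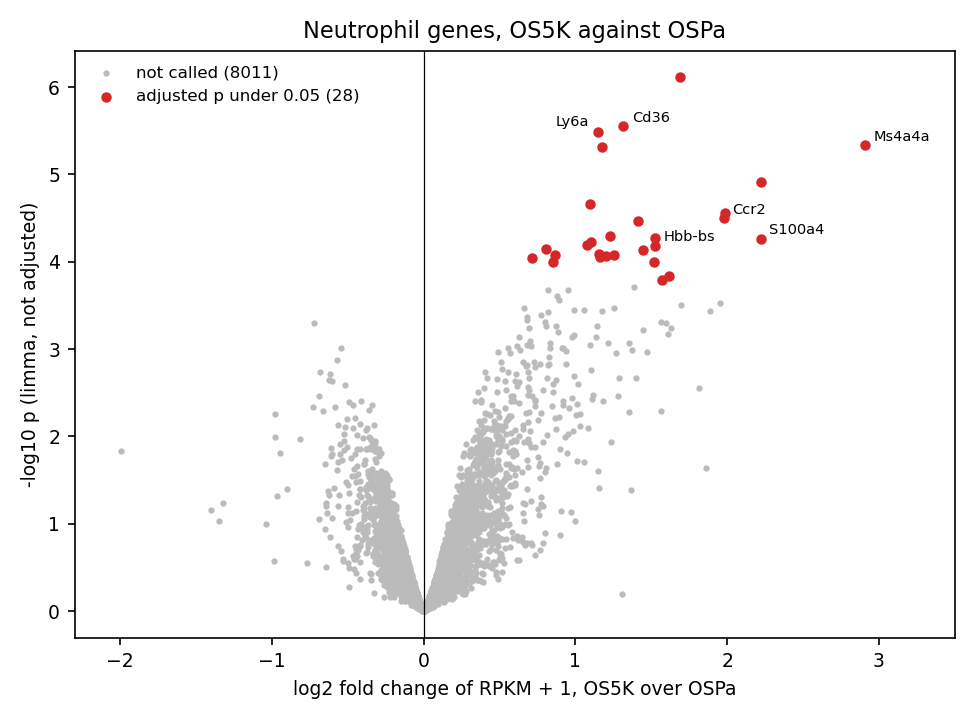
Each point is 1 of the 8039 tested genes, with the log2 fold change of RPKM + 1 for OS5K over OSPa on the x axis and -log10 of the unadjusted limma p on the y axis. The 28 genes with an adjusted p under 0.05, in red, all lie right of 0, between 0.71 and 2.91.

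Among the 21 fixed markers of erythroid cells, 14 could be tested and 13 were higher in OS5K than in OSPa, with a median log2 fold change of 1.52 (camera adjusted p = 6.3e-18, adjusted p = 0.25 with an estimated correlation). Over all genes 5 of them were called, and 11 were when adjusted over the list alone. The beta-globin genes Hbb-bs (log2 fold change 1.52, SE 0.22, limma adjusted p = 0.030) and Hbb-bt (1.51, SE 0.23, adjusted p = 0.031) rose together. Under 16 other settings their log2 fold changes ran from 0.60 to 1.68 and from 1.27 to 1.76. These genes are close paralogs, so the split of reads between them is uncertain. Fech is a member of this list too. Reads of the 4 adult hemoglobin genes made up 1.89 ± 0.429% of all reads in OSPa (SD, n = 2), 4.47 ± 0.470% in sham (n = 2) and 5.34 ± 2.14% in OS5K (n = 6). Every OS5K library (lowest 3.46%, highest 9.52% in OS5K #1 replicate 1) lay above both OSPa libraries (highest 2.19%). The difference of this share between OS5K and OSPa, in percent, gave an exact permutation p of 0.107 (two-sided, smallest possible 0.0357). That test treats the libraries as interchangeable, though the 6 OS5K libraries belong to 3 lines. Other called genes linked to iron were Isca1, which assembles iron-sulfur clusters (1.23, SE 0.17), and Slc25a37, a mitochondrial iron importer (0.81, SE 0.12), both with an adjusted p of 0.030.

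Monocyte and macrophage markers were higher in OS5K in 18 of 19 tested members, with a median log2 fold change of 0.49 (camera adjusted p = 7.5e-11, adjusted p = 0.25 with an estimated correlation). The test over all genes called 2 of them, and 12 were called when adjusted over the list alone. Ccr2, the receptor that brings monocytes out of the bone marrow, rose from 0.460 ± 0.161 RPKM (SD, n = 2) to 5.50 ± 3.78 (SD, n = 6), a log2 fold change of 1.98 (SE 0.26, adjusted p = 0.028). Ms4a6c rose by 1.98 (SE 0.26, adjusted p = 0.028). Outside the list, Ms4a6d rose by 2.22 (SE 0.26, adjusted p = 0.016), and it shares sequence with the other Ms4a6 genes, so its reads are uncertain. Also called were S100a4 (2.22, SE 0.32), a calcium-binding protein, Lgals1 (1.42, SE 0.19), which encodes galectin-1, and Cd36 (1.32, SE 0.13), a receptor for fatty acids and lipoproteins. Abundant monocyte genes were not called, with log2 fold changes of 0.02 for Csf1r (SE 0.13, adjusted p = 0.999) and 0.06 for Ly6c2 (SE 0.17, adjusted p = 0.999).

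Further called genes were Tlr7, a receptor for single-stranded RNA (1.26, SE 0.19, adjusted p = 0.030), Ly6a, the surface antigen Sca-1 (1.15, SE 0.12, adjusted p = 0.0077), Ube2l6, the enzyme that hands on the ubiquitin-like protein Isg15 (1.57, SE 0.26, adjusted p = 0.047), and Fam46c, a poly(A) polymerase (1.53, SE 0.22, adjusted p = 0.030). Under 16 other settings these calls were kept in 11, 14, 4 and 11, so most alternatives ended that of Ube2l6, the fewest kept for any of the 28 genes. The 5 falls of smallest p, none past the threshold, were Zfp971 (-0.57, SE 0.13, adjusted p = 0.128), Stfa2 (-0.68, SE 0.16, 0.148), Pim1 (-0.62, SE 0.14, 0.154), Piwil2 (-0.60, SE 0.15, 0.166) and Klf2 (-0.41, SE 0.11, 0.219).

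**Figure D2:**
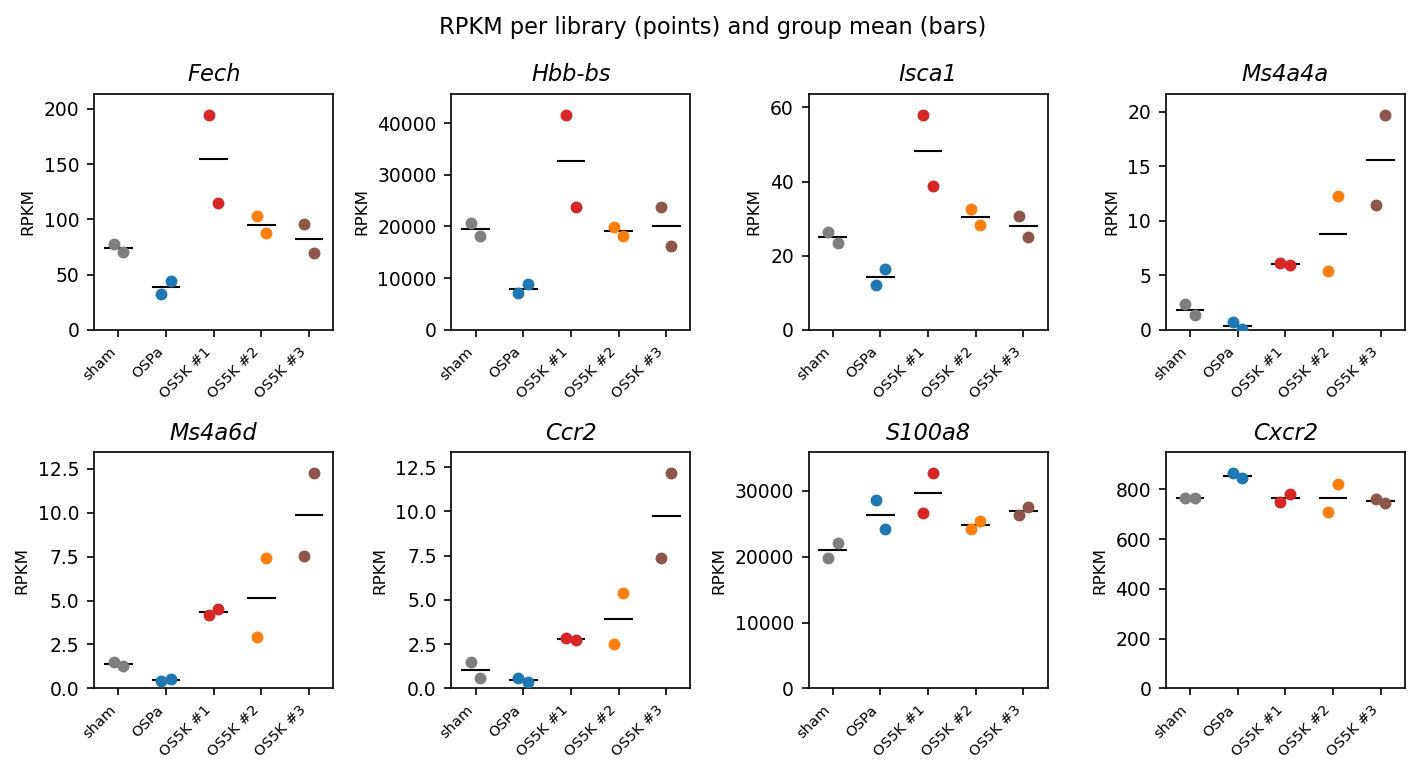
RPKM of 8 genes, on linear axes that start at 0, for each of the 10 libraries (points) with the mean of each group of 2 (bars). For Fech the OSPa libraries lie at 32.3 and 44.4 RPKM, under both sham libraries and all 6 OS5K libraries, while S100a8 overlaps between OSPa and OS5K and the OSPa libraries are the highest for Cxcr2, at 863 and 846 RPKM, a difference that did not pass the test.

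Of the 29 fixed lists with at least 5 tested members, camera with a preset correlation called 12 for OS5K against OSPa, 8 higher and 4 lower. None was called with an estimated correlation (smallest adjusted p = 0.250) or by fry (smallest 0.0503). Fry's other test, for changes of members in either direction, was not used for calls. Over the 12 lists its adjusted p ran from 0.00026 (lipid genes) to 0.559 (interferon-gamma), with 0.0062 for erythroid and 0.0027 for monocyte markers. Cytosolic ribosomal protein genes were higher in 63 of 68 members (median 0.25), mitochondrial respiration genes in 34 of 41 (median 0.16) and lipid genes in 18 of 23 (median 0.16), with an adjusted p of 0.610, 0.665 and 0.322 with an estimated correlation. In the lipid list 1 gene was called over all genes, Cd36, and 4 adjusted over the list alone. The interferon-gamma list was lower in 22 of 22 members (median -0.27, adjusted p = 0.671 with an estimated correlation), with 0 members called by limma over all genes or over the list alone. Without OSPa replicate 2 the count of lists was 6, none of them lower, and the interferon-gamma call was lost (adjusted p = 0.962). The other lists called lower were genes of circulating mature neutrophils (median -0.15), glycolysis and hypoxia (-0.11) and the response to STAT3 and G-CSF (-0.14). All 3 calls were lost without OSPa replicate 2, with an adjusted p of 0.0967, 0.174 and 0.391, and stood at 0.349, 0.582 and 0.582 with an estimated correlation. Quantile normalization also ended the first of them (0.122).

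Platelet markers were higher in 15 of 16 members in OS5K (median 0.62, adjusted p = 0.697 with an estimated correlation), a call that was lost without OSPa replicate 1 (adjusted p = 0.723, with the direction turned), OS5K #1 replicate 2 (0.164), OS5K #2 replicate 1 (0.124) or OS5K #3 replicate 2 (0.120). Of 5 eosinophil markers, 4 were higher and 1 lower (median 0.28), with 3 called higher and 1 lower when adjusted over the list alone. Markers of dendritic cells and MHC class II were higher in 7 of 8 members (median 0.41). The calls of the eosinophil and the dendritic list had an adjusted p of 0.497 and 0.665 with an estimated correlation. Both were lost without OSPa replicate 2 (0.132 and 0.0875), and the latter also without OSPa replicate 1 (0.156). B-cell markers were not called, with 8 of 14 members higher and a median of 0.05 (camera adjusted p = 0.915).

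Against OSPa, the OS5K lines were also tested singly. For OS5K #1 the test called 28 genes, 27 higher and 1 lower, the unnamed transcript Gm47718 (log2 fold change -0.89, SE 0.14, adjusted p = 0.039). Large rises were those of Ms4a4a (2.39, SE 0.37, adjusted p = 0.039) and Alas2, the first enzyme of heme synthesis in red cell precursors (2.26, SE 0.37, 0.049). For OS5K #3 it called 16 genes, all higher, among them Ms4a4a (3.57, SE 0.37, adjusted p = 0.012) and Tlr7 (1.54, SE 0.23, 0.044). OS5K #2 gave 0 calls with limma, 530 genes at an unadjusted p under 0.05 and 1 call with limma-voom on recovered reads. Among those of smallest p was Ly6a (1.11, SE 0.14, adjusted p = 0.0914). At an unadjusted p under 0.05 there were 492 genes for OS5K #1 and 794 for OS5K #3.

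These counts moved with single libraries. For OS5K #1 the count was 0 without OSPa replicate 1, 7 without OSPa replicate 2, 1 without its own replicate 1 and 16 without either replicate of OS5K #3. For OS5K #3 it was 0 without either OSPa replicate, 0 without its own replicate 1 and 1 without its own replicate 2. It was 4 with limma-voom, 7 with the filter at 5 RPKM and 50 with only the groups compared in the fit. For OS5K #2 it was 1 without either sham replicate and 2 without its own replicate 1. A call for 1 line and not for another does not show that they differ. The direct test among the 3 lines called 0 of 8039 genes (limma F test, smallest adjusted p = 0.732), with 535 at an unadjusted p under 0.05 and 0 calls with limma-voom on recovered reads. The smallest p belonged to Slfn5, an interferon-induced gene, Xrn2, a nuclear exonuclease, the unnamed transcripts Gm43796 and 2610524H06Rik, and Ighd, the heavy chain of immunoglobulin D.

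To ask what the parental tumour itself changed, OSPa was set against sham. Limma called 0 genes, with 480 at an unadjusted p under 0.05, 137 higher and 343 lower, and limma-voom on recovered reads also called 0. Stfa2, a stefin-type inhibitor of cysteine proteases, stood at 193 ± 34.1 RPKM in OSPa and 93.7 ± 5.01 in sham (SD, n = 2 each), a log2 fold change of 1.02 (SE 0.19, limma adjusted p = 0.558). It belongs to a family of close copies, so its reads are uncertain. Dusp2, a phosphatase of MAP kinases, stood at 2.27 ± 0.883 against 5.87 ± 0.231 (log2 fold change -1.10, SE 0.20, adjusted p = 0.558). The other genes of smallest p were Ccdc125 (0.57), Gsr (0.51), Ctnnbip1 (0.60) and Scamp1 (0.56) on the higher side and Yif1a (-0.91), Ly6a (-0.79), Sec61g (-0.82) and Rpa2 (-0.69) on the lower side. Without sham replicate 1 the count was 3, without sham replicate 2 it was 1, and with no filter on low values it was 9.

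Erythroid markers were lower in OSPa than in sham in 12 of 14 members, with a median of -0.95 (camera adjusted p = 3.8e-07, adjusted p = 0.509 with an estimated correlation). None was called over all genes, and 8 were when adjusted over the list alone, Hbb-bt (-1.39, SE 0.29) and Hbb-bs (-1.30, SE 0.27) having the smallest p. Monocyte markers were lower in 18 of 19 members (median -0.30), mitochondrial respiration genes in 37 of 41 (median -0.23) and immediate early genes in 23 of 30 (median -0.26), with an adjusted p of 0.509, 0.560 and 0.509 with an estimated correlation. Type I interferon genes were lower in 40 of 40 members (median -0.49, camera adjusted p = 2.0e-11, adjusted p = 0.509 with an estimated correlation), a call lost without sham replicate 2 (0.258). Interferon-gamma genes were lower in 20 of 22 (median -0.58, adjusted p = 0.560 with an estimated correlation). That call was lost without OSPa replicate 1 (0.413), and without sham replicate 2 the list was called higher (adjusted p = 0.0354).

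In all, camera called 16 lists for OSPa against sham, 6 higher and 10 lower, 9 without OSPa replicate 2, and 0 with an estimated correlation (smallest adjusted p = 0.509) or by fry (0.343). NF-kB targets (median -0.24), ribosomal protein genes (-0.24), dendritic cell and MHC class II markers (-0.56) and B-cell markers (-0.36) made up the rest of the lower lists. The NF-kB call was lost without sham replicate 2 (0.555) or OSPa replicate 1 (0.0736), the ribosomal one without sham replicate 1 (0.0676) or OSPa replicate 2 (0.220), the dendritic one without sham replicate 1 (0.442), and the B-cell one without sham replicate 1 (0.311, direction turned) or OSPa replicate 2 (0.683). Higher lists were genes of circulating mature neutrophils (median 0.15), lost without sham replicate 1 (0.0631), tertiary granule genes (0.14), lost without OSPa replicate 2 (0.247), and platelet markers (0.42), lost with the direction turned without sham replicate 2 (0.758) or OSPa replicate 2 (0.999). Secondary granule genes (0.22), genes of granulocytic myeloid-derived suppressor cells (0.11) and glycolysis genes (0.04) were each lost under quantile normalization (0.179, 0.373 and 0.130) and without OSPa replicate 2 (0.435, 0.282 and 0.858). The first and last were also lost without sham replicate 2 (0.237 and 0.238), and the other without sham replicate 1 (0.483).

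The last comparison set the OS5K groups against sham. Limma called 0 genes, with 838 at an unadjusted p under 0.05, 441 higher and 397 lower, and limma-voom on recovered reads called 0. Mmp8, the neutrophil collagenase, stood at 442 ± 49.8 RPKM in OS5K (SD, n = 6) and 282 ± 9.98 in sham (SD, n = 2), a log2 fold change of 0.64 (SE 0.09, limma adjusted p = 0.148). Slfn5, an interferon-induced gene, stood at 36.5 ± 12.4 against 59.6 ± 9.72 (-0.76, SE 0.13, adjusted p = 0.148). Other genes of small p were Ptp4a1 (0.91), Nap1l1 (0.72) and Cpne2 (0.71) on the higher side and Isyna1 (-0.70), Scimp (-0.96), Trim30c (-1.03) and Oas2 (-0.69) on the lower side. The count was 30 without sham replicate 1, 4 higher and 26 lower, and 2 without sham replicate 2 or with no filter on low values.

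Interferon genes were lower in OS5K than in sham. Members of the type I interferon list were lower in 36 of 40 (median -0.52, camera adjusted p = 2.0e-13, adjusted p = 0.545 with an estimated correlation) and those of the interferon-gamma list in 21 of 22 (median -0.93, camera adjusted p = 1.1e-11, adjusted p = 0.545 with an estimated correlation). Over all genes 0 members were called by limma, and 20 and 15 when adjusted over the list alone. Gbp3, an interferon-induced GTPase, stood at 2.67 ± 0.651 RPKM in OS5K (SD, n = 6) and 11.9 ± 9.87 in sham (SD, n = 2). Both list calls were lost without sham replicate 2 (adjusted p = 0.0546 and 0.116), as was that for NF-kB targets (median -0.36, 0.0976 without it, 0.545 with an estimated correlation).

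Camera called 11 lists for OS5K against sham, 6 higher and 5 lower, 6 without sham replicate 2, and 0 with an estimated correlation (smallest adjusted p = 0.545) or by fry (0.342). Erythroid markers were higher in 14 of 14 members (median 0.51, camera adjusted p = 1.5e-05) and immediate early genes lower in 23 of 30 (median -0.20), both with an adjusted p of 0.545 with an estimated correlation. Platelet markers were higher in 15 of 16 (median 0.95, 0.612 with an estimated correlation), lost without sham replicate 2 (0.0686), and B-cell markers lower in 11 of 14 (median -0.37, 0.877 with an estimated correlation), lost with the direction turned without sham replicate 1 (0.520). Monocyte markers (median 0.17) and lipid genes (0.11) were lost without sham replicate 2 (0.0976 and 0.116), and without OS5K #2 replicate 2 (0.0531) and OS5K #3 replicate 1 (0.0563) in turn. Tertiary granule genes (0.09) were lost under quantile normalization (0.0503) and without sham replicate 1 (0.386), OS5K #2 replicate 2 (0.122) or OS5K #3 replicate 1 (0.0873). NADPH oxidase and antioxidant genes (0.09) were lost under quantile normalization (0.0723), without either sham replicate (0.0520 and 0.0850), and without OS5K #1 replicate 1 (0.140), OS5K #2 replicate 2 (0.0531) or OS5K #3 replicate 1 (0.0586).

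**Figure D3:**
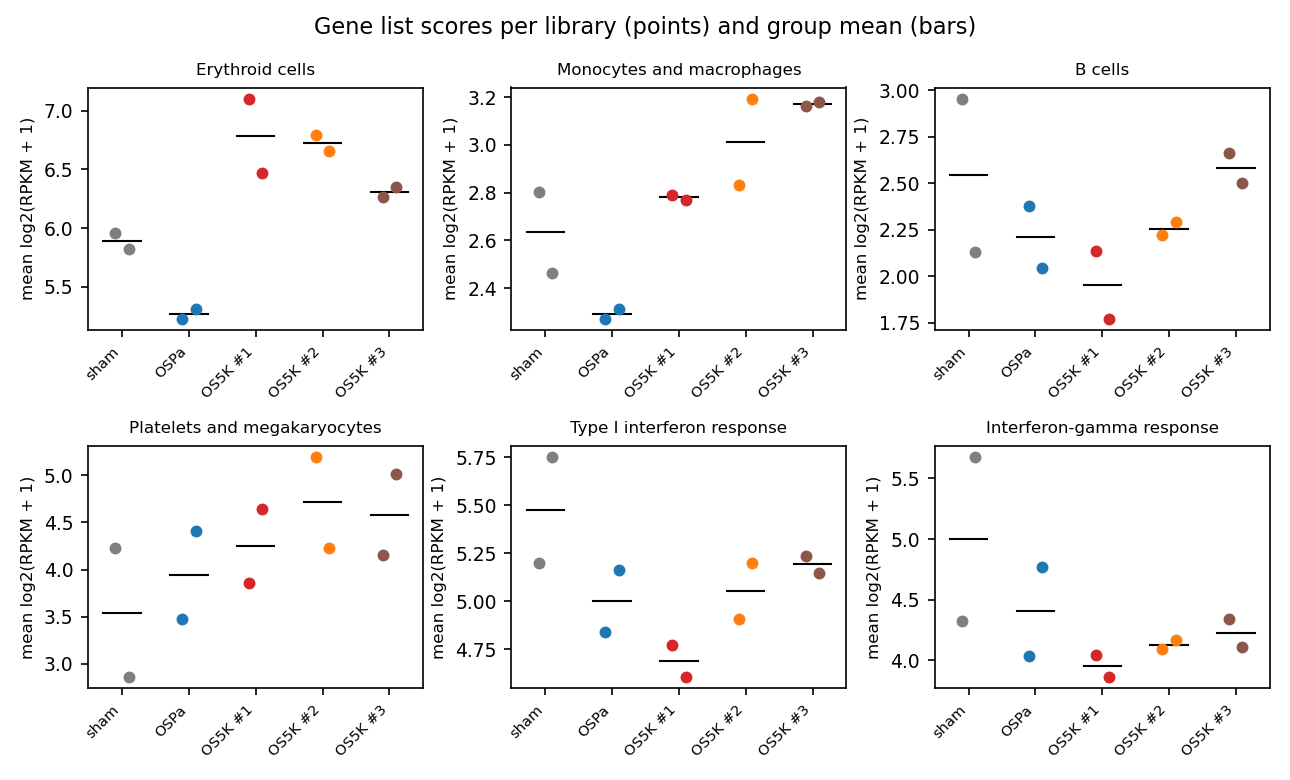
Mean log2(RPKM + 1) over the tested members of 6 fixed lists, for each of the 10 libraries (points) with the mean of each group of 2 (bars); the y axes do not start at 0. The OSPa libraries are the lowest for erythroid and for monocyte markers, and the sham libraries lie far apart for interferon-gamma genes.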

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

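Limma-voom on recovered reads, totals without hemoglobin reads, the joined Hba-a genes and the crossed pairing were chosen after the data were seen. Genes called for OS5K against OSPa numbered between 20 and 37 under the other scalings, tools, pseudocounts and the stricter filter. With no filter the counts were 15 for OS5K against OSPa (4 of the 28 kept), 9 for OSPa against sham, 2 for OS5K against sham, 13 and 14 for OS5K #1 and #2 against OSPa and 7 among the lines. For OS5K #3 the stricter filter gave 7, the fit with only the groups compared 50 and limma-voom 4, and limma-voom gave 1 for OS5K #2. The OS5K mean without OS5K #1 gave 13. Lists called with an estimated correlation or by fry were 0 in each comparison. Estimated correlations ran from -0.029 (neutrophil extracellular trap genes) to 0.85 (platelet markers), with 0.44 for erythroid and 0.20 for monocyte markers, against the preset 0.01. Why the other counts moved was not tested.

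With 1 library left out, and a lone library assumed to vary like the other groups, counts ran from 1 to 60 (OS5K against OSPa), 0 to 3 (OSPa against sham), 0 to 30 (OS5K against sham), 0 to 41, 0 to 2 and 0 to 17 (OS5K #1, #2 and #3) and 0 to 0 among the lines. Lists ran from 6 to 15, 9 to 20 and 6 to 12. Deviations of the replicate 1 libraries from their group means correlated between groups at values from -0.38 to 0.45. These values showed no common pairing by number, and they cannot exclude one in some groups. The replicate block gave 21, 0, 0, 23, 0, 14 and 0 genes and 12, 16 and 11 lists in the same order. The crossed pairing, fitted on 4 libraries, gave 0 for OSPa against sham, 23 for OS5K #1 and 47 for OS5K #3, against 0, 29 and 50 without it. Scaling moved the median of all genes by less than 0.1. Genes without 1 RPKM in at least 2 libraries were tested only in the setting with no filter. The planned count-only alternatives were not run because the unit was RPKM.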

Other observations

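The tests in this part were chosen after the results were seen, except that leaving out each library was planned. Some secondary granule transcripts differed within groups. Ltf, which encodes lactoferrin, stood at 27.97 RPKM in OS5K #1 replicate 2, 22.9 in OS5K #2 replicate 1 and 20.47 in OS5K #3 replicate 2, and between 80.9 and 135 in the other 7 libraries. Camp, the cathelicidin precursor, stood at 39.9, 28.6 and 28.6 in those 3 libraries, and Ngp, another granule protein, at 184, 142 and 121, against a lowest value elsewhere of 90.1 for Camp and 350 for Ngp. Lcn2 did not follow, with 291, 195 and 178, and the score of the whole list of 17 secondary granule genes split less, with 5.98, 5.82 and 5.74 as mean log2(RPKM + 1) in the 3 libraries against 6.06 to 6.52 elsewhere. The same 3 libraries had the highest platelet scores, 4.65, 5.19 and 5.01, against 2.85 to 4.41 elsewhere. Their shares of mitochondrial reads were also the highest, at 0.137% (95% Wilson interval 0.135 to 0.139), 0.136% (0.134 to 0.138) and 0.144% (0.142 to 0.146) against 0.0598% (0.0585 to 0.0610) to 0.0982% (0.0966 to 0.0998) elsewhere, with intervals that cover counting error only. They also stood alone at the high end of the first principal component (25.6% of the variance), at 12.4, 10.6 and 19.7 against at most 0.0856 elsewhere. Each OS5K line holds 1 of the 3 and sham and OSPa hold none, so the OS5K side of the comparisons includes this split. The platelet call for OS5K against OSPa was lost when each of the 3 was left out, and also without OSPa replicate 1. The values fall into separate clusters, so no pooled correlation is given.

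Reads of the alpha-globin copies were split unevenly. Hba-a2 ranged from 11.4 RPKM in OSPa replicate 2 to 7569 in OS5K #2 replicate 1, while Hba-a1 stood at 17367 and 26416 in these libraries. The copies are nearly identical, so the split is uncertain.

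Erythroid genes were higher in OS5K than in OSPa, though the list was not called with an estimated correlation (adjusted p = 0.25) or by fry (0.0503). A lower share of neutrophils, which raises the RNA of other blood cells alike, stays open. Log2(RPKM + 1) shrinks the change of low genes, so lists of unlike level would not move alike even then. The erythroid list stood at another level than the B-cell list (scores 5.27 and 2.21 in OSPa), so differences of its score cannot decide it. The erythroid score rose without overlap and by over 2 SE above only 1 of the 5 other cell types, B cells (1.29, SE 0.34, exact permutation p = 0.0714, smallest possible 0.0357). It rose by over 2 SE but with overlap above dendritic cells (1.00, SE 0.25), monocytes (0.64, SE 0.30) and eosinophils (0.70, SE 0.35). Monocyte (0.70) and eosinophil (0.64) scores were also higher in every OS5K library (exact permutation p = 0.0357 each, adjusted over the lists 0.173). Platelet (0.57, exact p = 0.25), dendritic (0.34, exact p = 0.357) and B-cell scores (0.05, SE 0.25, exact p = 0.857) overlapped. The mature neutrophil score was lower but did not pass (-0.19, exact permutation p = 0.0357, adjusted over the lists 0.173). These exact tests ignore that the OS5K libraries came in lines. Red cell RNA carried through the sort stays open: over the 10 libraries the hemoglobin share followed the 10 other erythroid markers with r = 0.948 (permutation p = 0.00011), rho = 0.927 (permutation p = 0.00031) and r = 0.792 without the 2 farthest libraries, but both follow the groups, so this would arise whatever the source. Within groups, the replicate with more hemoglobin reads had the higher mean of the other markers in 5 of 5 groups (exact sign p = 0.0625, the smallest that 5 groups allow, so a p under 0.05 was out of reach), and whether the tumour line or the handling of the OSPa samples set the level is untested.

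Monocyte genes were higher in OS5K too. A lower share of neutrophils stays open here as well, since the comparisons with the other cell types were mixed. The monocyte score rose without overlap and by over 2 SE above only 1 of the 5 other cell types, B cells (0.65, SE 0.20, exact permutation p = 0.0357, the smallest possible). The B-cell and monocyte lists stood at a like level in OSPa (scores 2.21 and 2.29), so unequal shrinkage does not account for this difference. For these lists it argues against a rise of all other cell types alike. The monocyte score moved with eosinophils (difference 0.06, SE 0.11), which goes with such a rise. Monocytes passing the gate and a change in the neutrophils themselves stay open: the 17 markers outside the called genes had a median log2 fold change of 0.459, 16 of them higher, but this largely restates the change of the whole list (median 0.49), which was not called with an estimated correlation (adjusted p = 0.25). Csf1r at 0.02, Ly6c2 at 0.06 and Ctss at 0.22 moved little, and no table here gives their level in neutrophils alone, so they decide nothing.

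Interferon lists were lower in OS5K than in sham, and 1 sham library may set this. Without sham replicate 2 the median of the type I list was -0.177, with 4 of 6 OS5K libraries under the sham library left, and without sham replicate 1 it was -0.78. For the interferon-gamma list the medians were -0.239, with 5 of 6 OS5K libraries lower, and -1.53. With 2 sham libraries that differ this much, a high sham library and an effect of the tumours cannot be told apart.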
